A study of Mus musculus with 2 samples.

How the data were processed

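Single-cell RNA profiles of live CD45-positive cells sorted from digested aortas were available as 2 libraries of Ldlr-/- mice during regression of atherosclerosis, 1 control and 1 treated with anti-miR-33. The libraries were 10x Chromium 3′ v2 libraries per the labels, and the number of mice in each was not given. The values are raw UMI counts per gene and barcode, as deposited, with no normalization, and per the file headers they are integers written with software version 3.0.0. The submitters' processing notes name Cell Ranger, Seurat and the mm10 genome build. The deposited barcodes had already been reduced to cells, with a lowest total of 502 UMIs in the control and 501 in the anti-miR-33 library, by a filter that was not stated.

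Cells with at least 200 genes and under 10% mitochondrial UMIs were used, which left out 34 and 19 control and 63 and 31 anti-miR-33 barcodes. The median mitochondrial share of the others was 2.01% and 2.27%. Doublets were scored with Scrublet in each library. Its automatic threshold marked 0 and 1 cells, so the cells with the highest scores were left out at an expected rate of 0.8% per 1000 barcodes (4.34% and 4.86%; 236 and 295 cells). Cells with over 10% haemoglobin UMIs were left out (13 and 20). The libraries were clustered together on log-normalized counts of 2000 variable genes without mitochondrial, ribosomal protein, haemoglobin and antigen receptor genes, with 30 principal components, 15 neighbours and a Leiden resolution of 1. Each cluster took the fixed marker list with the highest mean score, if at least 3 of its markers were detected and no other list had more markers among the cluster's top 10 genes, and stayed unnamed otherwise. Macrophage-like cells, and T-cell-like, NK-cell-like and type 2 innate lymphoid-like cells, were clustered again in the same way, and a subcluster also needed a marker of its list among its top 10 genes. Subclusters with 2 or more markers of another class there, and more than of their own list, were called mixed; macrophage, monocyte and type 2 conventional dendritic markers did not count as another class for macrophage subclusters, nor T-cell, NK-cell and type 2 innate lymphoid markers for lymphoid ones. Names are resemblances to marker lists.

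Counts were summed per library and class, since cells are not replicates, and given as CPM. Folds have conditional binomial intervals and shares Clopper-Pearson intervals, at the 95% level. A share of 0 is given with the limit that 3 counts allow. No test was made, because each group had 1 library. For 31 gene lists, and for genes with a miR-33 seed match of 7 nucleotides in the 3′ UTR (GENCODE vM21 annotation of GRCm38), the median log2 fold of members with at least 20 UMIs over both libraries was placed among 10000 random lists matched in 25 bins of expression. Members were counted as higher or lower by at least 1.5-fold. Counts of cycling cells and of cells with a gene were made after thinning each cell to 1000 UMIs and also unthinned.

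Genes were named by a rule. In macrophage-like cells, genes with at least 200 UMIs over both libraries, seen in at least 20 cells and with no cell holding over 10% of the UMIs (4796 genes) were ranked, and the 12 largest and 12 smallest folds were named. In other classes with at least 100 cells in each library the minimum was 100 UMIs, and the 5 largest and 5 smallest were named. For macrophage lists outside the central 95% of their random lists, the 4 members farthest from 0 in that direction were named, and Abca1, Abcg1, Foxp3, Trem2, Mki67, Cd68 and Ldlr always. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin, T-cell receptor variable, Xist and Y-linked genes and genes with provisional names were left out of the ranking.

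Filters, markers, gene lists, the naming rule and a first set of alternatives were fixed before the data were examined. Choices made after seeing the data were the doublet rate in place of the automatic threshold, the haemoglobin limit, the removal of mixed subclusters from their class, and the immature T-lineage clusters, defined by summed CPM of Rag1, Rag2, Dntt, Ptcra, Arpp21 and Ccr9 above 500 in clusters whose best list was T cell or that had at most 1 marker of their best list among their top 10 genes. The plasmacytoid dendritic-like cluster passed the threshold on CPM and kept its name by its 4 markers. Alternatives were TMM and median-of-ratios scaling, the mean over cells, no minimum on counts, thinning, doublets kept, at least 500 genes, under 5% mitochondrial UMIs, Leiden resolutions of 0.5 and 2, each library clustered alone, assignment of each cell by its marker score, 3 cycle genes, thinning to 2000 UMIs, an 8-nucleotide seed match and random lists also matched on UTR length. Alternatives added later were a threshold of 1000 CPM for the immature clusters, shares without these clusters, mixed subclusters kept, the latter 2 together, each macrophage subcluster at its pooled share, subclusters made without the subclass markers, and cells with an immature T-lineage transcript left out.

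The fold intervals and list percentiles were tested on simulated data with 200 changed genes among 5042. Intervals covered 95.4% of unchanged genes, the median estimate was 1.99 for a 2-fold and 4.05 for a 4-fold change, and the 24 genes named were all changed ones. Of 200 unchanged lists 3.5% lay outside, and of 100 lists shifted by 1.3-fold 100% lay above. The simulation held counting noise and no variation between mice. Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, igraph 0.11.9, matplotlib 3.10.9, scikit-image 0.26.0, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0 were used.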

Results

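Live CD45-positive leukocytes were sorted from the aortas of Ldlr-/- mice, a strain that lacks the LDL receptor and is prone to atherosclerosis, while their lesions were regressing, and were profiled by droplet single-cell RNA sequencing. There were 2 libraries, 1 from control mice and 1 from mice given anti-miR-33, an oligonucleotide that inhibits miR-33, a microRNA that represses the cholesterol exporter Abca1. The comparison addresses which leukocytes, and which genes within them, differed between regressing aortas with and without miR-33 inhibition. The control library held 5480 barcodes and 26485435 UMIs, and the anti-miR-33 library 6166 barcodes and 22447398 UMIs. Cells that passed the filters had a median of 3477 UMIs and 1183 genes in the control library and of 2428 UMIs and 940.5 genes in the anti-miR-33 library, and 5178 and 5759 cells were kept after doublet removal. The labels did not state how many mice each library came from. With 1 library per group no difference could be set against the spread between replicates, so none was tested. Intervals are exact 95% intervals for shares (Clopper-Pearson) and for folds of summed counts (conditional binomial), and cover counting error only. Folds and ratios are anti-miR-33 over control throughout.

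Immature T-lineage clusters, set apart by antigen receptor recombination genes such as Rag1 and Dntt, made up 47.0% of the anti-miR-33 cells (95% interval 45.7 to 48.3) and 9.41% of the control cells (8.62 to 10.2), a ratio of 5.001 (4.54 to 5.52). These were 2709 and 487 cells in 4 clusters, with median depths of 1021 and 1186 UMIs. The largest cluster, led by Rag1, Cd8b1, Arpp21, Dntt and Ccr9, held 66.9% of them in the anti-miR-33 and 61.4% in the control library. A cycling cluster led by Hist1h2ap, Pclaf and Ube2c held 16.9% and 19.1%. A cluster led by Itm2a, Lef1 and Satb1 held 13.7% and 16.0%, and one led by Gm4632, Myl10 and Tcrg-C2 2.55% and 3.49%. Prss34 and Mcpt8, genes of basophils, were also among the leading genes of 2 of these clusters. Whether the immature cells came from the aorta itself or from thymus tissue taken with it could not be decided, as given with the flagged results. Macrophage-like cells, the phagocytes that take up lipid in lesions, made up 27.4% of control and 12.8% of anti-miR-33 cells, a ratio of 0.47 (0.43 to 0.51). T-cell-like cells, outside the immature clusters, made up 28.5% and 17.4%, and B-cell-like cells 10.7% and 5.30%. Because the immature clusters lowered every other share, shares were also taken without them, over 4691 control and 3050 anti-miR-33 cells. On that basis macrophage-like cells were at 30.3% and 24.2% (ratio 0.80, 0.73 to 0.87). With the macrophage subclusters that carried T-cell or B-cell genes kept, they were at 33.2% and 31.5% (0.95, 0.87 to 1.03), so that a lower share rested on leaving these out. B-cell-like cells were at 11.8% and 10.0% (0.85, 0.74 to 0.98) and T-cell-like cells at 31.5% and 32.9% (1.04, 0.96 to 1.13).

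Among the smaller classes without the immature clusters, plasmacytoid dendritic-like cells, producers of type I interferon, made up 0.469% of control and 0.951% of anti-miR-33 cells (ratio 2.03, 1.13 to 3.70; 22 and 29 cells), or 1.19 (0.66 to 2.16) over all kept cells. Their cluster held 895.65 CPM of the genes that set the immature clusters apart, more than the 824.3 of 1 immature cluster, and kept its name by its own markers. The type 2 innate lymphoid-like cluster also held transcripts of the mast cell proteases Cma1, Tpsb2 and Mcpt4. The ratios of type 2 innate lymphoid-like cells (0.74), NK-cell-like cells (0.88), monocyte-like cells (0.85), conventional dendritic-like cells of type 1 (1.10) and type 2 (1.22) and neutrophil-like cells (1.23) had intervals that included 1. The CD45 sort set which cells could be seen, and the immature clusters had the lowest median depth of the classes compared, so that the filters on cells bear most on their share. The immature clusters were set apart by a threshold chosen after the data were seen, as were macrophage clusters mixed with T-cell or B-cell genes, which held 2.63% of control and 3.85% of anti-miR-33 cells, or 8.74% and 23.1% of the cells named macrophage. Kept in their class, the mixed cells brought the macrophage ratio over all kept cells to 0.55. With each library clustered alone the ratio for macrophage-like cells was 0.71 and that for T-cell-like cells 0.29, and with each cell assigned by its marker score the T-cell ratio turned to 1.62.

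**Figure D1:**
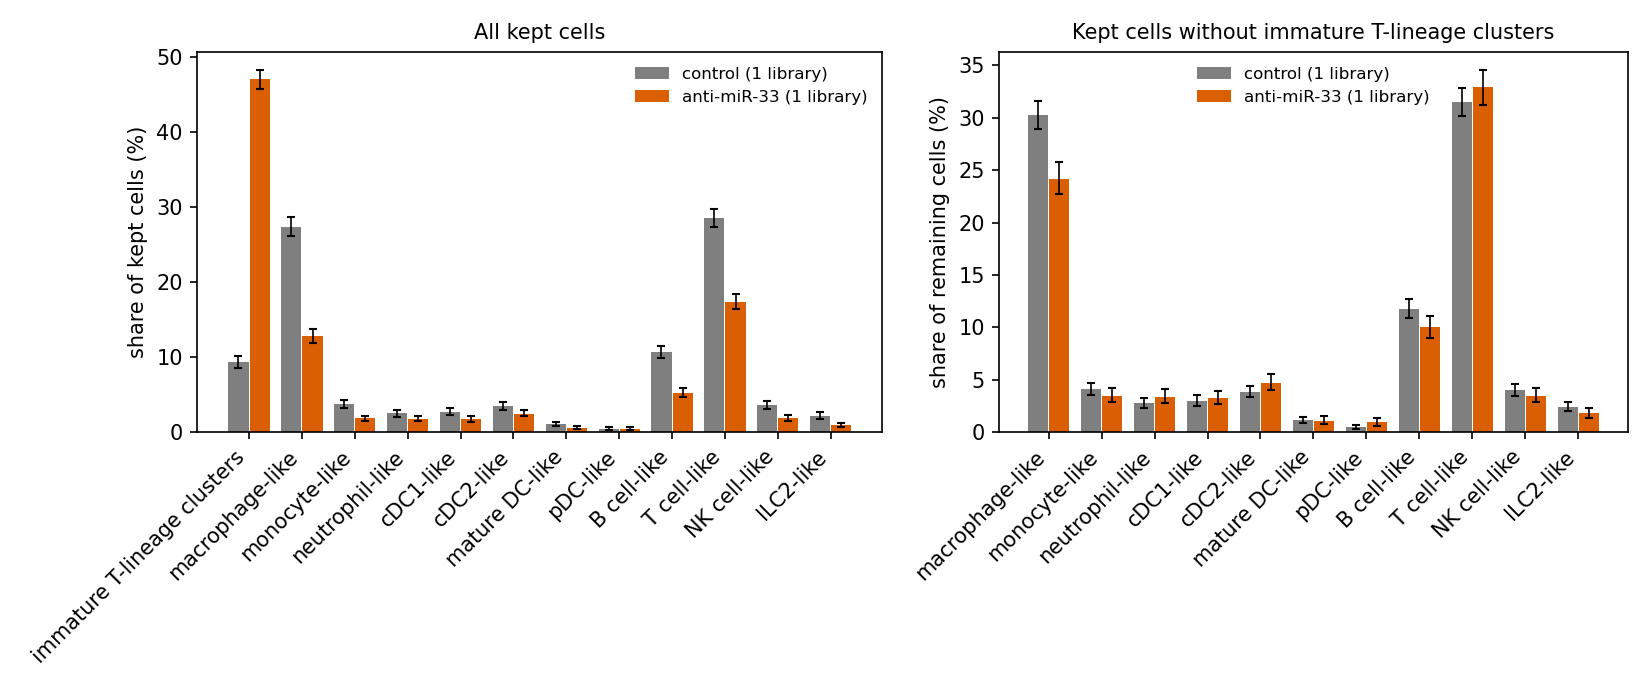
Share of cells (percent, vertical axis) in each cell class for the control and the anti-miR-33 library, over all kept cells (left) and without the immature T-lineage clusters (right), with exact 95% binomial intervals that cover counting error only. The immature clusters stand at 9.41% and 47.0% on the left. Macrophage-like cells, without the mixed subclusters, stand at 27.4% and 12.8% on the left and 30.3% and 24.2% on the right.

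Within macrophage-like cells, resident-like cells, marked by Lyve1, F13a1, Cbr2 and Ccl8, made up 16.0% of the control (14.1 to 18.0) and 28.2% of the anti-miR-33 macrophages (24.96 to 31.6), a ratio of 1.76 (1.45 to 2.14). Trem2-high foamy-like cells, the lipid-laden macrophages marked by Spp1, Gpnmb, Cd5l and Fabp5, were equally frequent at 36.6% and 36.7% (1.00, 0.86 to 1.16). MHC class II-high cells, which present antigen, made up 20.6% and 15.0% (0.73, 0.58 to 0.91). They comprised a subcluster led by Il1b, Ccl12 and H2-Eb1 (14.6% and 9.89% of macrophage-like cells) and one with 1 marker of its list among its leading genes, which included those of type 2 conventional dendritic cells and monocytes, such as Cd209a, Mgl2, Clec10a, Plac8 and Ccr2 (5.92% and 5.15%). Interferon-responsive cells numbered 30 of 1420 and 8 of 738. The marker genes themselves differed within these subclasses, by 1.13-fold in resident-like, 1.12-fold in Trem2-high and 0.83-fold in MHC class II-high cells. With subclusters made without these markers, but still named by them, the ratios were 1.84, 1.04 and 0.52. Different subclusters held most macrophages in the 2 libraries: in the control the largest was a Trem2-high one led by Spp1, Gpnmb and Ctsk (21.1% of macrophage-like cells), and in the anti-miR-33 library a resident-like one led by Saa3, Retnla, Cxcl13 and Lyve1 (26.0%). Unnamed subclusters held 19.8% and 14.4%. The proliferating subcluster, in which the neutrophil proteases Elane and Prtn3 were also among the leading genes, is not compared in size because its markers were lower in the anti-miR-33 library (a fold of 0.62).

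**Figure D2:**
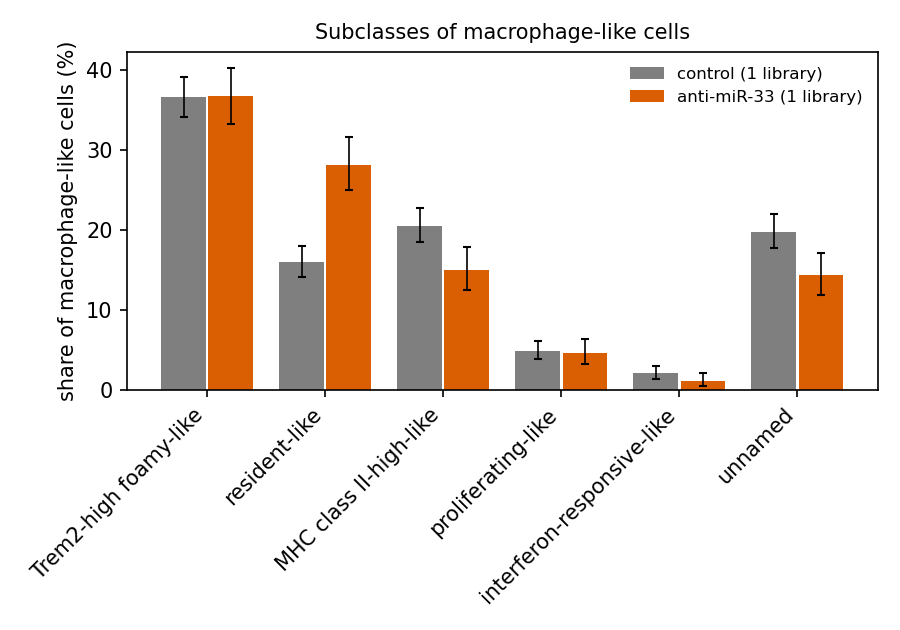
Share of macrophage-like cells (percent, vertical axis) in each subclass for the control and the anti-miR-33 library, with exact 95% binomial intervals that cover counting error only. Resident-like cells stand at 16.0% and 28.2% and Trem2-high foamy-like cells at 36.6% and 36.7%; the proliferating-like share is drawn but not compared.

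Among T-cell-like, NK-cell-like and type 2 innate lymphoid-like cells pooled (1780 control and 1165 anti-miR-33 cells), CD4 T-cell-like cells, helper cells led by Tnfrsf4, Izumo1r and Cd40lg, made up 14.7% of the control (13.1 to 16.5) and 7.55% of the anti-miR-33 cells (6.10 to 9.22), a ratio of 0.51. They were 1 subcluster, and other subclasses may hold CD4 cells too. Over all T-cell-like cells Cd4 itself stood at 32.7 CPM in the control and 28.9 in the anti-miR-33 library (134 and 77 UMIs). Naive T-cell-like cells, marked by the lymph node homing genes Ccr7 and Sell, made up 18.3% and 26.0% (1.42, 1.21 to 1.67). They comprised a subcluster led by Igfbp4, Dapl1 and Ccr7 (212 and 243 cells), on which the higher share rested, and one led by the NK-cell receptor genes Klra7, Klra9 and Klra1, with Sell and Dapl1 (113 and 60 cells). CD8 T-cell-like cells, cytotoxic cells led by Gzmk and Ccl5, made up 28.2% and 32.8% (1.16, 1.02 to 1.33). Gamma-delta or type 17 T-cell-like cells made up 25.1% and 22.7%. The CD8 ratio turned to 0.90 at a Leiden resolution of 0.5 and to 0.80 with doublets kept. Foxp3, the transcription factor of regulatory T cells, had a UMI in 15 of 262 control CD4 T-cell-like cells (5.73%, 3.24 to 9.27) and in 5 of 88 anti-miR-33 cells (5.68%, 1.87 to 12.8). Thinned to 1000 UMIs, these shares were 3.14% and 3.45%. Over all T-cell-like cells Foxp3 had a UMI in 18 of 1478 control (1.22%) and 5 of 1003 anti-miR-33 cells (0.50%), a ratio of 0.41 (0.12 to 1.14). Thinned, those shares were 0.62% and 0.30%. B-cell-like cells, which should lack Foxp3, had none in 553 and 305 cells, which allows a share of up to 0.542% and 0.984%, at median depths of 3159 and 3002 UMIs against 2389.5 and 2183 in the CD4 cells.

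Cells with UMIs of at least 2 cell cycle genes were counted after each cell was thinned to 1000 UMIs. They made up 44.0% of control (38.3 to 49.8) and 48.2% of anti-miR-33 immature T-lineage cells (45.5 to 50.8), with 187 and 1301 shallower cells left out. In macrophage-like cells they made up 14.6% (12.8 to 16.6) and 15.9% (13.3 to 18.9), with 30 and 42 left out, and in T-cell-like cells 21.3% and 24.7%, with 25 and 4 left out. Unthinned, the shares were 41.1% and 40.6% in immature, 64.2% and 66.4% in macrophage-like and 60.3% and 63.7% in T-cell-like cells. Among CD8 T-cell-like cells the share was 24.0% and 31.8% (ratio 1.32, 1.02 to 1.72), with 7 and 1 left out, or 63.5% and 70.7% unthinned. The CD8 ratio had intervals that included 1 unthinned (1.11, 0.94 to 1.31), thinned to 2000 UMIs (1.05, 0.85 to 1.299) and with 3 genes (1.496, 0.91 to 2.46), and a CD8 subcluster led by Gzma and Gzmb, with the cell cycle genes Pclaf and Stmn1, held 2.79% and 8.38% of these cells. Free RNA of cycling immature cells was not removed from these counts, and whether it added to them is open.

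Within macrophage-like cells, Abca1, which exports cholesterol to apolipoprotein A-I and is a direct target of miR-33, stood at 117 CPM (UMIs scaled to a common library total) in the control (109 to 124) and 150 in the anti-miR-33 library (138 to 163), a fold of 1.29 (1.16 to 1.43; 1002 and 580 UMIs). It was higher in Trem2-high (1.25, 1.09 to 1.44) and resident-like cells (1.38, 1.07 to 1.77), and at 1.23 (0.85 to 1.76) in MHC class II-high cells. Abcg1, a second exporter that loads cholesterol onto HDL, did not differ at this depth (1.02, 0.92 to 1.13), nor did the macrophage marker Cd68 over all macrophage-like cells (1.03, 0.98 to 1.07), and both folds turned just under 1 with TMM scaling (0.96 for each). Within Trem2-high cells Cd68 was at 1.11 (1.05 to 1.17) and within resident-like cells at 0.89 (0.77 to 1.02). Trem2, a lipid-sensing receptor, was at 0.90 (0.86 to 0.93) over all macrophage-like cells. It was at 0.97 (0.92 to 1.01) within the Trem2-high cells that held most of its UMIs, and lower in resident-like (0.70, 0.61 to 0.80) and MHC class II-high cells (0.67, 0.56 to 0.79). Abca1 had a UMI in 40.1% and 45.8% of macrophage-like cells, or 11.01% and 15.2% after thinning, against 5.42% and 7.54% of B-cell-like cells, at median depths of 5101 and 4251.5 UMIs against 3159 and 3002. Ldlr had 7 and 4 UMIs and Foxp3 0 and 1, too few to compare. Abca1 (ENSMUSG00000015243) lies on chromosome 4 of GRCm38 at 53030787 to 53159895 on the minus strand. Its 3′ UTR of 3156 nucleotides, in exon 50 of 50, holds 3 matches to the miR-33 seed, at 53033802 to 53033808, 53033797 to 53033803 and 53033787 to 53033793. Of these, 2 are matches of 8 nucleotides. Abcg1, which did not differ, is on the list of miR-33 targets too, and its 3′ UTR of 3703 nucleotides holds 2 matches, 1 of them of 8 nucleotides.

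**Figure D3:**
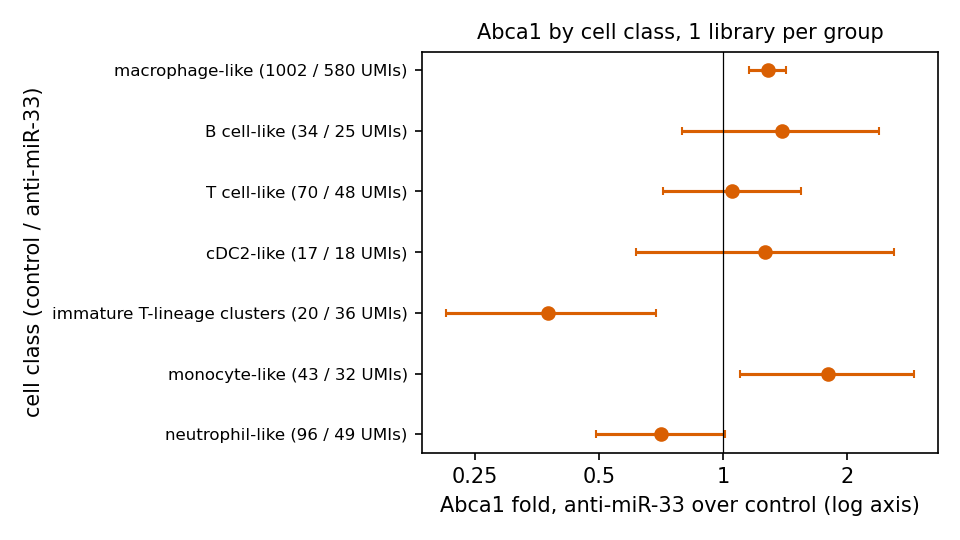
Abca1 fold (anti-miR-33 over control, horizontal log axis) of UMIs summed over the cells of each class and scaled to CPM, with exact 95% conditional binomial intervals that cover counting error only, in the compared classes with at least 20 Abca1 UMIs in the 2 libraries together. In macrophage-like cells it stands at 1.29 and in immature T-lineage cells at 0.38.

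Of the 12 genes with the largest folds in macrophage-like cells, 3 belong to tissue-resident or alternatively activated macrophages. These were Lyve1, a hyaluronan receptor (3.91, 3.25 to 4.73), the eosinophil-attracting chemokine Ccl24 (3.57) and Cd163, the scavenger receptor for haemoglobin (2.71, 2.26 to 3.26). With each subcluster held at its pooled share they were 2.26, 2.10 and 1.63, so part of each fold went with the larger resident-like share. The other 9 were T-lineage or lymphoid genes: the T-cell receptor constant genes Trbc2 (4.46), Trbc1 (3.96) and Trac (2.62), Cd8b1 (4.24), the receptor signalling genes Lck (3.49) and Lat (3.16), and Ly6d (3.14), Thy1 (3.01) and Cd24a (2.64). With doublets kept, Cd8b1 stood at 2.56, Ly6d at 1.76, Thy1 at 1.93 and Trac at 1.74, and with the mixed subclusters kept Lat stood at 5.12. T-cell markers summed over macrophage-like cells were 3.23-fold (3.03 to 3.45) and the 6 immature T-lineage genes 8.51-fold higher (6.44 to 11.4). Haemoglobin transcripts were 2.21-fold higher in macrophage-like cells and 1.48-fold to 2.92-fold higher in each of the other classes compared, beside every fold given here.

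The 12 smallest folds in macrophage-like cells held inflammatory, immediate early and mitotic genes. Il1b, which encodes the inflammatory cytokine IL-1β, was at 0.49 (0.40 to 0.58), and its fold was 0.60, 0.50 and 0.51 within Trem2-high, resident-like and MHC class II-high cells. It was also lower in 6 of 6 other classes measured. Because free RNA was not removed, these classes may not be independent of the macrophage-like cells, and whether the fall was particular to the latter is open. Dusp1 (0.43, 0.39 to 0.48) and Fos (0.55, 0.50 to 0.61) are induced within minutes of stimulation. Ly6a, an interferon-inducible surface protein, was at 0.42, the cold-inducible RNA-binding gene Cirbp at 0.51, the cell cycle inhibitor Cdkn2a at 0.53, Pianp at 0.56, the interferon-inducible Ifi213 at 0.57 and the chemokine Cxcl14 at 0.58. The mitotic genes Nusap1 (0.42), Ube2c (0.47) and Cenpf (0.54) and the proliferation marker Mki67 (0.58, 0.40 to 0.83) were lower too. Doublets weighed on these: with doublets kept, Nusap1 stood at 0.96, Cenpf at 0.83 and Mki67 at 1.05. The make-up of the class differed too. A macrophage cluster led by Elane, Hist1h2ap and Birc5, with 0 macrophage markers among its top 10 genes, held 4.30% of control and 2.17% of anti-miR-33 macrophage-like cells (61 and 16 cells). Clustered again, the proliferating subcluster held 4.93% and 4.61%, with the limit on its size given above. Within Trem2-high, resident-like and MHC class II-high cells Nusap1, Cenpf and Mki67 had at most 7 UMIs in either library, too few to compare. Ube2c was at 3.49 (1.11 to 11.9) in Trem2-high and 3.77 (1.43 to 11.6) in resident-like cells. These folds rest on 6 and 9 and on 6 and 18 UMIs, which a few cells may hold, so no direction is read from them. Ly6a was at 0.69 with the mixed subclusters kept, and with each cell thinned to 1000 UMIs Cdkn2a was at 0.31 and Pianp at 0.999.

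The median log2 fold of each of 30 gene lists was placed among 10000 random lists of the same size matched on expression, as a description of these 2 libraries. In macrophage-like cells 8 lists lay below and 4 above the central 95% of their random lists. Genes of the type I interferon response were lower (median −0.29, 1 of 29 members higher and 5 lower by at least 1.5-fold), with the chemokine Cxcl10 at 0.27 (0.10 with doublets kept), Ifi44 at 0.49, the interferon regulator Irf7 at 0.59 and Stat2 at 0.62. NF-kB and inflammatory cytokine genes were lower (−0.17, 1 of 21 higher and 3 lower), with Tnfaip3, an NF-kB feedback inhibitor, at 0.45, Osm at 0.59 and the inflammatory caspase Casp4 at 0.70 (0.77, 0.36 and 0.43 with thinning). Among MHC class II genes (−0.13, 3 of 12 higher and none lower) the abundant Cd74, H2-Aa, H2-Eb1 and H2-Ab1 were at 0.72, 0.74, 0.75 and 0.77. Of MHC class I genes (−0.22, 3 of 15 lower), H2-Q7 and H2-Q4 were at 0.64, the peptide transporter Tap1 at 0.65 and H2-T22 at 0.79. Immediate early genes were lower (−0.23, 4 of 20 lower), with Fosb at 0.30 (0.12 with thinning) and Btg2 at 0.66, and mitochondrially encoded genes lay below their random lists (−0.14, none of 13 lower by at least 1.5-fold), with mt-Atp8 at 0.75, mt-Atp6 at 0.85, mt-Nd3 at 0.88 (1.02 with thinning) and mt-Nd2 at 0.89. Genes of G2 and M phase were lower (−0.60, 13 of 25 lower), led by Hmmr at 0.37, Bub1b at 0.41 and Kif23 at 0.46 (0.14, 1.33 and 0.89 with thinning), but their median was −0.07 with doublets kept. Whether the smaller share of the cycling cluster led by Elane set the G2 and M phase median was not tested. Within Trem2-high, resident-like and MHC class II-high cells this median was 0.21, 0.54 and 0.16 over 4, 5 and 4 measured members, with none lower and the resident-like one above its random lists. The share of thinned macrophage-like cells with at least 2 cell cycle genes was not lower, whereas with 3 genes it was 6.55% and 5.75% (ratio 0.88, 0.59 to 1.29). Efferocytosis genes, which serve the clearance of dead cells, lay just below their random lists (−0.06, 4 of 23 higher by at least 1.5-fold and none lower), with Axl at 0.82, Anxa1 at 0.87 and Tgm2 at 0.88, and turned to between 0.03 and 0.04 under 4 other settings.

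Heat shock genes were higher in macrophage-like cells (median 0.36, 2 of 13 higher by at least 1.5-fold), with Hsph1 at 1.64, the endoplasmic reticulum chaperone Hspa5 at 1.56, Hspd1 and Hspa1a at 1.42. Hspa1a was at 3.73 within Trem2-high cells but at 0.52 and 0.49 within resident-like and MHC class II-high cells, whereas the other 3 stood above 1 in each. Alternative activation genes were higher (0.24, 6 of 16 higher and 1 lower), with Ear2 at 2.18 (1.31 under 5% mitochondrial UMIs) and Retnla at 1.96 beside Ccl24 and Cd163. Retnla was at 1.16 with each subcluster at its pooled share and at 1.01 without cells that held an immature T-lineage transcript. Lysosome genes lay above their random lists (0.09, against −0.04 to 0.06; 1 of 29 higher and 1 lower), though their median was −0.02 with the mixed subclusters kept. Their highest members were the protease Ctsl at 1.59, Atp6ap1 at 1.28, Psap, the precursor of the saposins, and Atp6v0c at 1.23, the last on 18 and 10 UMIs (0.74 as the mean over cells). The median log2 fold of all genes was 0.08, and it shifted to −0.02 with TMM or median-of-ratios scaling, under which the lysosome median turned to −0.01. Random lists shift alike, so the positions of the lists did not rest on the scaling. Cytotoxicity genes were higher (0.56, 4 of 9 higher), with Gzmb at 5.86, Gzma at 2.18, Cst7 at 2.05 (1.32 as the mean over cells) and Klrd1 at 1.94 (1.12 under 5% mitochondrial UMIs), beside NK-cell markers at 2.14 (1.54 to 2.97) and T-cell markers at 3.23 in these cells, but Gzmb was at 0.999 and their median was −0.00 once cells were thinned to 1000 UMIs. The miR-33 targets (0.08, percentile 54.7) and the cholesterol efflux and LXR targets (0.12, percentile 87.8) lay inside their random lists, and the miR-33 target median turned to −0.02 with either scaling. Inside as well lay lipid uptake and storage (0.11), cholesterol biosynthesis (0.10), fatty acid oxidation (0.08), oxidative phosphorylation (0.00), glycolysis (0.09), autophagy (0.04), chemokines (0.01), matrix remodelling (0.15), adhesion and migration (0.08), apoptosis (0.08), S phase (0.18), hypoxia (0.10), iron and oxidative stress (0.02), S100 and calprotectin (0.09), T-cell activation (−0.12) and regulatory T-cell function (0.21). The signs of fatty acid oxidation, oxidative phosphorylation, glycolysis, autophagy, chemokines, adhesion, apoptosis, iron and S100 genes turned with either scaling, and those of cholesterol biosynthesis and hypoxia with median-of-ratios factors.

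**Figure D4:**
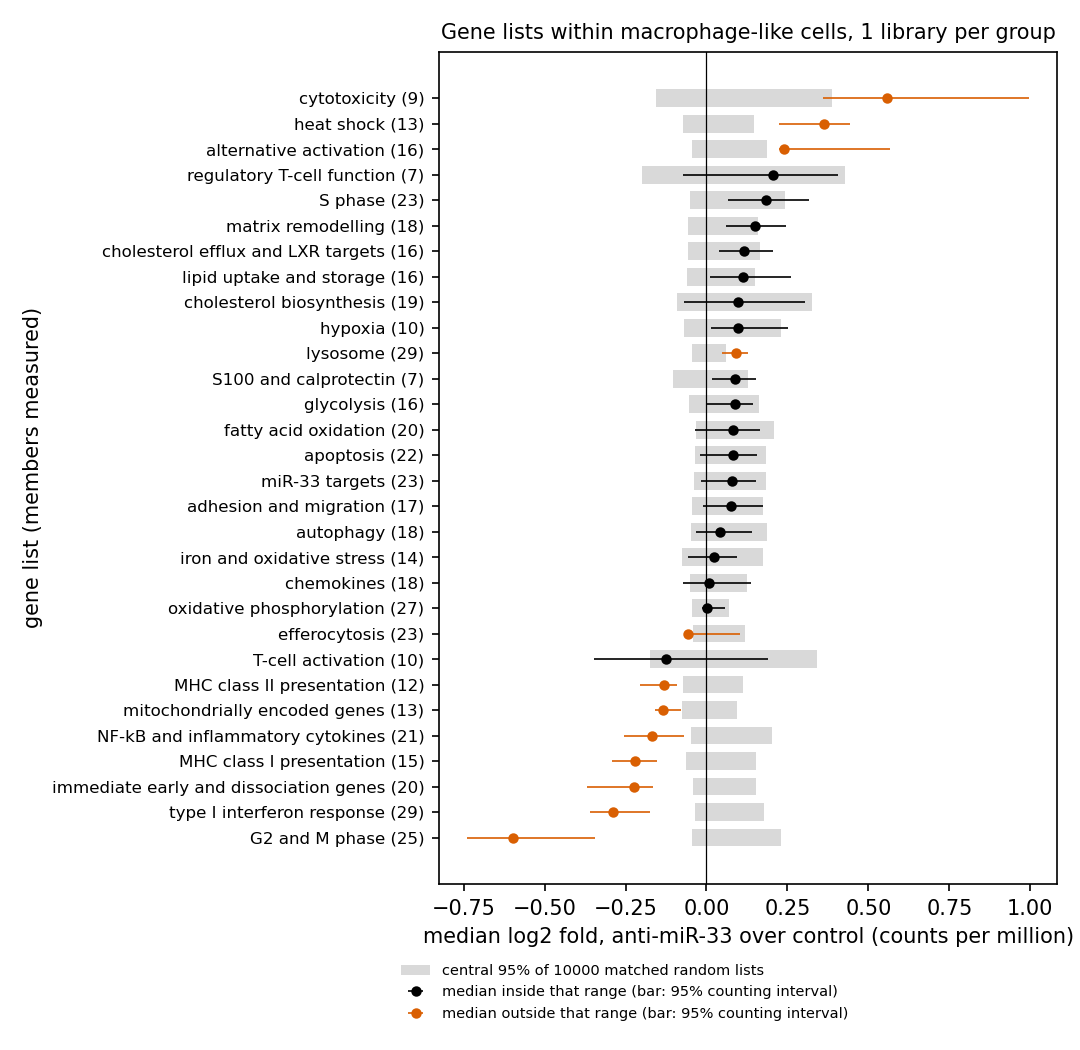
Median log2 fold (anti-miR-33 over control, horizontal axis) of 30 gene lists in macrophage-like cells, each over the central 95% of the medians of 10000 random lists matched on expression (grey), with bars for the 95% interval of counting error; medians outside the grey range are orange. Heat shock stands at 0.36 and the type I interferon response at −0.29, outside their random lists, whereas the miR-33 targets at 0.08 lie inside theirs. The lysosome median of 0.09 turns to −0.01 with other scaling.

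Several of these lists differed more within a subclass. In Trem2-high foamy-like cells the MHC class II median was −0.76 (6 of 11 members lower by at least 1.5-fold), with Cd74 at 0.55 and H2-Aa at 0.49. Cd74 was also lower in 6 of the other 8 classes, with 0.33 in immature T-lineage cells, and higher in 2. Whether free RNA, which was not removed, added to the Trem2-high folds was not tested. The type I interferon median in Trem2-high cells was −0.39 (8 of 21 lower). Heat shock genes (0.51, 6 of 13 higher), lysosome genes (0.18, 1 of 28 higher and 1 lower; Ctsl 1.77, Psap 1.40) and cholesterol efflux and LXR targets (0.18, percentile 98.0, 1 of 16 higher) lay above their random lists. In resident-like cells the MHC class II median was inside its random lists (0.07), alternative activation genes were higher (0.26, 4 of 15 higher) and immediate early genes lower (−0.43, 7 of 19 lower). Lysosome genes lay below their random lists there (−0.09, percentile 1.3), and the cholesterol efflux and LXR targets inside theirs on the lower side (−0.12, percentile 6.51). Chemokine (−0.34, 3 of 15 higher and 4 lower) and NF-kB genes (−0.28, 2 of 19 higher and 4 lower) had medians below their random lists with members in both directions. The list farthest above was cytotoxicity (1.74, 5 of 6 higher). The T-lineage genes Trbc2 and Cd8b1 were at 6.04 and 4.94 in the same resident-like cells, and Gzmb had 2 and 24 UMIs there. In MHC class II-high cells the median of the cholesterol efflux and LXR targets lay above its random lists (0.29, percentile 99.1, 3 of 14 higher and 1 lower). Type I interferon (−0.49, 6 of 20 lower) and NF-kB genes (−0.48, 1 of 18 higher and 6 lower) were lower. The MHC class II genes are also markers of that subclass, so their lower median there (−0.19) is not read as a result. In part this holds for other lists too. The alternative activation list shares Mrc1, Cd163 and Folr2 with the resident-like markers. With the Trem2-high markers the lysosome list shares Ctsd, Cd63 and Atp6v0d2, and the cholesterol efflux and LXR targets share Lpl. The medians of these lists in those subclasses are thus not independent of how the subclasses were named. The miR-33 targets lay inside their random lists in each of these subclasses (0.10, 0.21 and 0.08).

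Beyond known targets, genes with a miR-33 seed match in the 3′ UTR were compared with the others. A 3′ UTR was annotated for 20986 of 31053 genes (67.6%), and the 7-nucleotide match CAATGCA occurred in 1492 of them. In macrophage-like cells the 741 measured genes with a match had a median log2 fold of 0.10 against 0.08 for genes without, at the 91.6th percentile of their random lists, and at the 73.9th when these were also matched on UTR length. For the stricter 8-nucleotide match the median was 0.05, at percentile 7.21. Of the 9 classes, conventional dendritic-like cells of type 1 alone lay outside, with a median of −0.01 for genes with a match against 0.07 for the others, below all of the random lists, which turned to 0.02, inside them, for the 8-nucleotide match. The list of known miR-33 targets lay below its random lists in neutrophil-like (−0.25) and immature T-lineage cells (−0.14, or 0.15 without cells that held an immature T-lineage transcript) and inside in the other classes. In the other classes the medians with a match were 0.19 in B-cell-like, 0.04 in NK-cell-like, −0.05 in T-cell-like, 0.06 in type 2 conventional dendritic-like, 0.10 in monocyte-like, −0.06 in neutrophil-like and 0.01 in immature T-lineage cells, inside their random lists. With TMM scaling the median was 0.00 in macrophage-like cells and below 0 in B-cell-like (−0.05), NK-cell-like (−0.04) and monocyte-like cells (−0.02).

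In monocyte-like cells Abca1 was higher as well (1.80, 1.10 to 2.91; 43 and 32 UMIs). The largest folds there included Fabp4, a fatty acid-binding protein (2.14, 1.63 to 2.80), with Ly6d (2.44), Cd3d (2.15), Rbm42 (2.16) and Nsmce4a (1.91), and the smallest Fos (0.34), Ms4a7 (0.39), Nenf (0.40), Cirbp (0.41) and Slamf9 (0.43). Thinned, Nsmce4a was at 4.52, Fos at 0.17, Nenf at 0.10 and Slamf9 at 0.13. Monocyte-like cells had lower type I interferon genes (median −0.52, 11 of 25 lower by at least 1.5-fold) and higher lipid uptake and storage (0.47, 5 of 14 higher) and alternative activation genes (0.39, 5 of 13 higher). Beside these, T-cell markers were at 2.65 (2.31 to 3.03), NK-cell markers at 7.26, B-cell markers at 1.51, type 1 conventional dendritic markers at 0.69 and monocyte markers at 0.88 (0.84 to 0.92) in these cells. The median of all genes there shifted from 0.05 to −0.06 with TMM scaling. In neutrophil-like cells Abca1 was at 0.71 (0.49 to 1.01), which turned to 1.12 with thinning, and P2ry6 (0.35), Fos (0.39), Slamf9 (0.48) and Nupr1 (0.49) were lower (thinned, 0.21 for Fos, 0.82 for Slamf9 and 0.26 for Nupr1). This cluster also held macrophage markers, at 27998 CPM in the control against 50036 in macrophage-like cells, and in the anti-miR-33 library these were lower (0.77, 0.76 to 0.79) and neutrophil markers higher (1.32, 1.31 to 1.34), beside each of its folds. Alternative activation genes were higher there (0.60, 9 of 14 higher) and NF-kB genes lower (−0.46, 9 of 19 lower). Abca1 was at 1.39 in B-cell-like, 1.05 in T-cell-like and 1.26 in type 2 conventional dendritic-like cells, with intervals that included 1, and at 0.38 (0.21 to 0.69; 20 and 36 UMIs) in immature T-lineage cells (0.15 thinned), beside macrophage markers at 0.60 (0.57 to 0.63) and type 1 conventional dendritic markers at 0.33 in the same clusters. In type 1 conventional dendritic-like cells it had 13 and 1 UMIs (0.11, 0.00251 to 0.71).

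T-cell-like cells of the anti-miR-33 library had lower transcripts of activation: the effector cytokine Ifng was at 0.34 (0.21 to 0.54), the costimulatory receptor Tnfrsf9 at 0.33 (0.20 to 0.51), Tnfaip3 at 0.38 and Jun at 0.31. With doublets kept Ifng was at 0.10, and thinned Jun was at 0.48. The T-cell activation list had a median of −0.67 (9 of 16 members lower by at least 1.5-fold, none higher), the regulatory T-cell function list −0.44 (4 of 11 lower), and the chemokine list −0.60 (7 of 13 lower). The 2 libraries differed in the make-up of this class: the cluster led by Tnfrsf4 and Izumo1r held 15.6% of control and 8.37% of anti-miR-33 T-cell-like cells, and a CD8 subcluster led by Ccl1, Ccl4, Ccl3, Xcl1, Lag3, Ifng and Tnfrsf9 held 20 and 0 cells. Macrophage markers in T-cell-like cells were at 0.72 (0.69 to 0.75). Jun, and Nr4a1 of the activation list, are also on the immediate early list, whose median was below 0 in all 9 classes. Tnfaip3 was lower in macrophage-like cells and in 6 of 6 other classes measured, T-cell-like cells among them. Whether the transcripts were lower beyond these shifts was not tested. The largest folds were Ly6d (2.17), Trap1 (2.06), the granule protease Gzma (2.05), Gsn (1.90) and Scml4 (1.86), of which Gzma turned to 0.66 with doublets kept and Scml4 was at 1.16 thinned. In NK-cell-like cells the receptor Klra8 was at 1.82 (1.51 to 2.21), Pitpna at 1.91, the phosphatase Ptpn6 at 1.785, Cd8b1 at 1.76 and Tubb4b at 1.69, and Cirbp (0.46), Emb (0.48), Serpina3g (0.52), Lrrfip1 (0.54) and the transcription factor Stat4 (0.55) were lower. Thinned, Pitpna was at 3.48, Serpina3g at 0.34 and Lrrfip1 at 0.98. In immature T-lineage cells Tspyl4 (2.91), Rrp1b (2.83), Tns3 (2.64), Ifrd2 (2.45) and Nutf2 (2.44) had the largest and S100a4 (0.23), S100a6 (0.27), Lat2 (0.27), Ly6a (0.28) and Unc93b1 (0.30) the smallest folds. As the mean over cells, Rrp1b was at 6.84, Ifrd2 at 1.60, S100a4 at 0.39, S100a6 at 0.46, Ly6a at 0.52 and Unc93b1 at 0.54, and thinned Tspyl4 was at 5.11, Tns3 at 1.60 and Lat2 at 0.43. Nutf2 was at 3.77 without cells that held an immature T-lineage transcript. Their MHC class II genes, which belong to other cell types, were lower (−1.30, 10 of 10 lower).

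In conventional dendritic-like cells of type 1, which cross-present antigen, 18 of 18 measured G2 and M phase genes were higher by at least 1.5-fold (median log2 fold 2.04). Their member Hmgb2, at 2.09-fold (1.32 thinned), lay below that median. Cks1b (2.53-fold, or 1.64 thinned) and Stmn1 (2.185-fold), which are not on that list, were also higher. Beside these, the immature T-lineage genes were 3.70-fold (2.12 to 6.77) and T-cell markers 2.07-fold higher in these cells. The share of cells with cell cycle transcripts was 13.3% and 16.7% after thinning, with 5 and 4 cells left out, or 75.0% and 75.0% unthinned. Trbc2 (2.93) and Rgs18 (2.24) were also among their largest folds, and Dusp1 (0.27), Cirbp (0.37), Fcrla (0.44), Emc2 (0.48) and Fos (0.55) were the smallest (thinned, 6.56 for Trbc2, 3.75 for Rgs18, 0.94 for Fcrla and 0.31 for Emc2; Cirbp 0.65 as the mean over cells). Their median of all genes shifted from 0.07 to −0.04 with TMM scaling. In type 2 cells the lectin Mgl2 was higher (2.57, 2.26 to 2.93), and the sterol synthesis gene Fdps (0.36, 0.23 to 0.55), the NF-kB subunit Relb (0.49), Tbc1d4 (0.43, or 0.09 thinned), Dusp1 (0.39) and Ifitm6 (0.51) were lower. Cholesterol biosynthesis genes as a list were lower there (−0.89, 7 of 12 lower), as were NF-kB (−0.52, 8 of 17 lower and 1 higher) and type I interferon genes (−0.44, 7 of 24 lower), beside markers of mature dendritic cells at 0.62 (0.53 to 0.73) and of monocytes at 0.80 (0.75 to 0.85). Lat (4.55), Cd8b1 (4.197), Trbc2 (3.91) and Trac (2.68) had the other large folds in these cells, at 2.88, 1.45, 1.65 and 1.39 without cells that held an immature T-lineage transcript.

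B-cell-like cells had less immunoglobulin transcript in the anti-miR-33 library, 8.58% of UMIs in the control and 4.17% (a fold of 0.49), and plasma cell markers in the same cluster were at 0.53 (0.51 to 0.55). Bhlhe41, a transcription factor of B-1 cells, was at 0.38 (0.26 to 0.55), Junb at 0.47, S100a4 at 0.49, Atp2a3 at 0.52 and Sel1l at 0.53 (thinned, 0.89 for S100a4 and 0.92 for Sel1l). Their largest folds were T-cell genes, Lat (19.0), Tcf7 (15.0), Cd8a (14.4), Trbc2 (10.95) and Cd8b1 (9.31), and T-cell markers were 10.4-fold higher in sum. Without cells that held an immature T-lineage transcript these 5 folds were 8.61, 8.42, 6.06, 5.73 and 6.17, and with doublets kept 2.63, 3.19, 3.11, 3.24 and 3.68. The median of all genes in B-cell-like cells shifted from 0.20 to −0.04 with TMM scaling; relative to it, immediate early genes (−0.34, 6 of 15 lower and 1 higher) were lower and chemokine (1.41, 7 of 8 higher) and S phase genes (0.85, 14 of 21 higher) higher, though S phase turned to −0.44 with thinning and chemokines to −0.30 with doublets kept. Macrophage markers were 1.89-fold higher in these cells (1.81 to 1.97), beside the chemokine list. Neutrophil-like cells likewise had Cd8b1 (9.72), Trbc2 (5.77), Satb1 (4.35), Lat (3.77) and Trbc1 (3.62) as their largest folds, the last 4 at 3.23, 2.70, 1.48 and 2.04 without cells that held an immature T-lineage transcript and Cd8b1 at 4.15 thinned.

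Immediate early and dissociation-induced genes lay below their random lists in all 9 classes compared, from −0.23 in macrophage-like to −1.04 in immature T-lineage cells, with −0.60 in T-cell-like, −0.66 in type 1 and −0.47 in type 2 conventional dendritic-like, −0.48 in NK-cell-like, −0.31 in monocyte-like and −0.35 in neutrophil-like cells. Dusp1 was lower in 7 of the other 8 classes, with 0.35 in T-cell-like and 0.34 in neutrophil-like cells, and higher in NK-cell-like cells (1.59). Cirbp was lower in 8 of the other 8. Ly6a and Irf7 were also lower in 8 of 8 other classes, Fos in 7 of 7 and Il1b and Tnfaip3 in 6 of 6 measured, whereas Ifi213 was lower in 3 of 7. Type I interferon genes lay below their random lists in macrophage-like, monocyte-like, neutrophil-like, B-cell-like, both conventional dendritic-like and immature T-lineage cells, but the B-cell and type 1 dendritic medians (−0.10, 3 of 22 higher and 3 lower; −0.14, 1 of 20 higher and 2 lower) turned above 0 under some settings.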

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

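Of the tests in this part, those of the thymus and of cell pairs were set before their results were seen, and those of low depth, free RNA, tissue handling, library depth and subcluster shares were chosen after. Subclusters of macrophage-named cells that also carried T-cell genes such as Cd3g and Trbc2 held 14.3% of these cells in the anti-miR-33 library (137 of 960, 12.1 to 16.6) and 4.37% in the control (68 of 1556). Those with B-cell genes such as Igkc and Cd79a held 8.85% (85 cells, 7.13 to 10.8) and 4.37% (68 cells). Both were noted because they are a signal outside the classes compared that stood above the control level.

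Immature T-lineage clusters had a higher share in the anti-miR-33 library. Low-depth barcodes are argued against as the whole cause: among cells with at least 2000 UMIs the ratio of shares was 6.18 (5.15 to 7.46; 141 of 4128 control and 685 of 3245 anti-miR-33 cells). Thymus tissue taken with the aorta may have contributed, and the test could not decide it. Of the deep immature cells of the anti-miR-33 library, 25.4% (22.2 to 28.8) held UMIs of Cd4 and of Cd8a or Cd8b1. That lay between the bounds of over 50% and under 10% set for it (24.1% in the control, 2.08% in anti-miR-33 T-cell-like cells). Cd4 stood at only 148 CPM in the immature cells of that library, and the deep ones had a median of 4227 UMIs. Double-positive cells could thus lack a Cd4 UMI, and the upper bound was hard to reach. The limit of 2000 UMIs also favoured the cycling cluster (median 5894.5 UMIs) over the largest one (879). The most abundant genes of the thymus list were Cd8b1 (1421 and 1992 CPM), Cd8a (767 and 1064) and Dntt (571 and 679). Of its 14 genes 10 are in other lists and 6 stood at 10 CPM or more in control T-cell-like cells. Its members Aqp11 and Endou, outside the genes of the threshold but among the leading genes of the largest cluster, were nearly confined to the immature clusters. They stood at 242 and 287 CPM in control immature cells, against 1.71 each in control T-cell-like cells. These values set the clusters apart from other T cells and do not give their source. The CD45 sort would remove thymic stroma but keep thymocytes, while an effect of the treatment stays open as untested.

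T-cell genes were higher in macrophage-like cells of the anti-miR-33 library. Free RNA of immature T-lineage cells may be a source, as the folds of the immature genes had lower ends above 1.5 in 5 of 5 other classes tested (B-cell-like, NK-cell-like, both conventional dendritic-like and neutrophil-like cells). Monocyte-like cells were not among the classes tested, so a source shared by all cells was not shown. Cell pairs left after doublet removal stay open: the 5% of macrophage-like cells with most T-cell marker UMIs held 46.5% of them, between the bounds of over 50% and under 30%, and 56.8% in the control. A biological source was not tested.

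Immediate early genes were lower in the anti-miR-33 library. A difference in tissue handling between the 2 preparations may be the cause, but its test could not decide this. The median was below 0 by more than its counting interval in 9 of 9 classes. That count restates the pattern, and a treatment effect on all cells would give it too. A difference in depth is argued against, since the macrophage median was −0.33 with each cell thinned to 1000 UMIs (random lists −0.10 to 0.22). A difference in macrophage subcluster shares is argued against as the whole cause, since the median was −0.27 with each subcluster at its pooled share (random lists −0.03 to 0.15). With 1 preparation per group, handling and an effect of the treatment were not separated, and the latter stays untested.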

How the results depend on the processing

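Of the alternatives below, the pooled subcluster shares, the 1000 CPM threshold, shares without immature cells, mixed subclusters kept, both of these together, subclusters made without the subclass markers and leaving out cells with an immature T-lineage transcript were chosen after the results were seen. Across 345 results and 2855 values under alternatives, 54 were counted as reversed, 2322 of the others lay inside the counting interval of the reported value and 479 outside it. A value was counted as reversed if its direction changed, inside that interval or not, and the reported value had an interval without the value of no difference or, for lists and seed genes, lay outside its random lists. Changes of direction in other results are among those inside or outside the interval: of 2746 values with a direction 2617 had the reported one, 16 of 18 for macrophage subclasses and 35 of 45 for cycling shares. By kind, the reversed values were 4 of 708 for macrophage genes, 1 of 700 for genes of other classes, 37 of 1186 for gene lists, 1 of 45 for seed genes, 9 of 129 for class shares, 2 of 24 for lymphoid shares, 0 of 18 for macrophage subclasses and 0 of 45 for cycling shares. Where no cause is given below, the cause was not tested.

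Gene and list values are folds for genes and median log2 folds for lists. With TMM scaling the macrophage medians were 0.0183 for cholesterol efflux, 0.00463 for seed genes, −0.00673 for the lysosome and −0.0191 for miR-33 targets; with median-of-ratios factors they were 0.0130 for efflux, −0.0120 for the lysosome and −0.0243 for miR-33 targets. By construction these scalings shift all genes alike. With the 8-nucleotide match the seed medians were 0.0534 in macrophage-like and 0.0169 in type 1 dendritic-like cells (cDC1). As the mean over cells, efferocytosis was 0.0268 in macrophage-like cells, MHC class II −0.35 in NK-cell-like cells, and iron genes 0.15 in cDC1 and −0.26 in neutrophil-like cells.

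With doublets kept, Mki67 was 1.05 in macrophage-like and Gzma 0.66 in T-cell-like cells. The medians were −0.97 for MHC class II and 0.0365 for glycolysis in NK-cell-like cells, −0.30 for chemokines, −0.0858 for efferocytosis and −0.00919 for the lysosome in B-cell-like cells, 0.70 for chemokines in immature cells, −0.54 for cytotoxicity in T-cell-like cells and 0.02498 for interferon in cDC1. The CD8 ratio was 0.80.

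With each cell thinned to 1000 UMIs, macrophage folds were 1.33 for Bub1b, 0.999 for Gzmb and 1.02 for mt-Nd3, with medians of −0.00207 for cytotoxicity and 0.24 for miR-33 targets. In B-cell-like cells S phase was −0.44, the lysosome −0.00477 and interferon 0.14. In immature cells T-cell activation was 0.64 and adhesion 0.0406, in cDC1 chemokines were 0.68 and interferon 0.0179, in T-cell-like cells S phase was −0.0840, and in NK-cell-like cells MHC class II was −0.11. Fewer UMIs leave fewer counts by construction.

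Under 5% mitochondrial UMIs, MHC class II was −0.95 in NK-cell-like cells, chemokines −0.0136 and interferon 0.0127 in B-cell-like cells, and efferocytosis 0.0253 in macrophage-like cells. Without cells with an immature T-lineage transcript, MHC class II was −0.79 in NK-cell-like cells, S phase −0.17 and interferon 0.11 in B-cell-like cells, chemokines −0.23 and iron −0.35 in neutrophil-like cells, efferocytosis 0.0375 in macrophage-like cells and miR-33 targets 0.15 in immature cells. With each macrophage subcluster at its pooled share, efferocytosis was 0.0345 and miR-33 targets 0.16. With mixed subclusters kept, the macrophage lysosome median was −0.0152 and the macrophage ratio 0.55.

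The ratio of T-cell shares was 0.78 at a Leiden resolution of 0.5, 0.54 at 2, 1.62 with cells assigned by marker score, 0.29 with each library clustered alone, 0.79 at 1000 CPM for immature clusters, 0.69 with at least 500 genes and 1.04 without immature cells. The macrophage ratio was 0.40 at resolution 2, 0.71 clustered alone and 0.80 without immature cells, and the immature ratio 5.95 clustered alone. Without immature cells, which leave the denominator, the ratios of cDC1, type 2 dendritic-like and neutrophil-like cells were 1.10, 1.22 and 1.23. With mixed subclusters also kept, the macrophage ratio was 0.949, and those of T-cell-like, cDC1, type 2 dendritic-like and neutrophil-like cells were 1.04, 1.10, 1.22 and 1.23. The CD8 ratio was 0.90 at resolution 0.5, and the Trem2-high ratio 1.18 by marker score. With subclusters made without the subclass markers, but still named by them, the CD4 ratio was 0.39 and the MHC class II-high ratio 0.52. With 3 cycle genes the T-cell cycling ratio was 1.43.

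No paired analysis was possible because each group had 1 library. Median depth was 3477 UMIs in the control and 2428 in the anti-miR-33 library, which limits genes with few UMIs. The intervals leave out variation between mice, preparations and sequencing, and those of folds also leave out variation between cells.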

Other observations

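The lists and clusters named in this part were chosen after their values were seen, and no tests were added. In type 2 conventional dendritic-like cells matrix remodelling genes lay above their random lists (median 0.27, 2 of 12 higher by at least 1.5-fold), and so did heat shock genes (0.27, 1 of 10 higher and 2 lower, or 0.05 with thinning). Heat shock medians also lay above their random lists in type 1 conventional dendritic-like (0.31, 2 of 10 higher) and monocyte-like cells (0.24, 1 of 12 higher). In NK-cell-like cells efferocytosis genes were lower (−0.83, 4 of 8 lower), as were macrophage markers (a fold of 0.52, 0.46 to 0.58), and G2 and M phase genes were higher (0.90, 6 of 8 higher). Immature T-lineage genes, whose clusters include a cycling one, were higher in the same cells, with a lower end of their fold above 1.5.

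An unnamed cluster of 60 control and 62 anti-miR-33 cells was led by Retnla, Lyz1, Ear2, Ccl6 and Fn1 and held more markers of cavity macrophages than of the class with its best score. Non-immune cells, led by Dcn, Mgp and Sparc, numbered 23 and 42, which the CD45 sort sets rather than the tissue.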
